A study of Mus musculus with 105 samples.

How the data were processed

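Retina was measured before and at 12 h, 1 d, 2 d, 4 d, 1 week and 2 weeks after optic nerve crush, and eyecup before and at 12 h, 1 d and 2 d, in adult C57BL/6J mice and, for part of the retina libraries, in a cross that carries Vglut2-Cre and STP15. Cells were sorted by CD45 (immune cells), GLAST (Müller glia), CD140a (astrocytes) or gates that also took RGCs, and sequenced as 10x Chromium 3' libraries (v2, and v3 for the MC21 pair), per the labels. The authors deposited matrices of counts, whole numbers of UMIs per gene and cell, made with Cell Ranger 2.1.0 on GRCm38 per the submitters' processing notes; the filter on cells is not given in the sources used here. The deposited cell type labels of the retina tables were used as given. The label file of the eyecup held more labels than there were barcodes and did not run in step with them, so it was not used. All eyecup barcodes were therefore taken as RPE; 98.3% to 100.0% per library held a UMI of Rpe65, which free RNA can give too. Shares of eyecup cell types were not analysed here. This departs from the design set beforehand.

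The 105 GEO samples are lanes of 41 libraries, and the lanes of a library were summed. Libraries took their group from the time point and treatment in the labels. Some libraries share a title apart from a final number; the median over genes of the scaled squared difference between such pairs was 2.64 in microglia, 1.80 in astrocytes, 1.48 in Müller glia and 1.70 in RPE, against 16.6, 11.4 and 11.6 for other pairs of a group, so they may be channels of the same sample. Control replicates 4 and 5 share a title but differ like other pairs in microglia (12.1) and Müller glia (8.28), and in astrocytes (3.98) less than other pairs. Libraries of a title were kept apart, and their sum, these 2 included, was an alternative. Counts were summed per library and type: microglia with cycling and interferon classes, astrocytes, Müller glia with their interferon class, monocytes and macrophages, and RPE. Libraries with at least 50 cells of a type entered, and cells of the deposited low-UMI class were left out of these sums. GLAST libraries were left out for microglia and astrocytes. The deposited class of astrocyte and microglia doublets made up 0% to 3.82% per library of these 2 types with it. Doublets of Müller glia have classes of their own, and no caller was run.

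Genes were filtered with filterByExpr by time, scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with terms for time and strain and, for Müller glia, for the gate. Calls had a Benjamini-Hochberg adjusted p under 0.05 over the genes of a contrast. SEs were the log2 fold change over the square root of F. Contrasts were each time against control, and the mean of 12 h, 1 d and 2 d against that of 4 d, 1 week and 2 weeks, a contrast without the controls. Contrasts against control share the control libraries, so overlaps between them were not analysed here. Gene lists, 20 programme lists and 21 marker lists, were tested with limma 3.58.1 (camera on voom values, correlation 0.01), with camera at an estimated correlation and fry beside it, and adjusted over lists and times within a type. Lists are named in the text where camera called them at the preset correlation or the text says otherwise.

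Shares of immune types used libraries with at least 100 immune cells and two-sided exact permutation tests, adjusted over types and times. The difference between microglia and astrocytes was taken within a library as mean log2 CPM over a list and tested the same way. Müller glia were set against microglia as values only, as set beforehand, although part of the libraries hold both. States within types were compared only after the data had been seen. The MC21 pair has no replicates, so shares have exact binomial (Clopper-Pearson) and sums exact Poisson 95% intervals, and list medians a percentile among 10000 random lists matched in 20 bins of mean expression. A count of 0 was given the limit that 3 counts set. Cells were thinned to 1000 UMIs for the MC21 pair and to 5000 for eyecup barcodes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

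The tests, designs, gene lists, cell type markers, alternatives and the rule for named genes were fixed before the data were examined. The rule named, per type, the 8 highest and 8 lowest fold changes in the contrast with most calls (4 d in microglia and Müller glia, 12 h in astrocytes and RPE) among called genes at 50 CPM or more with every library of that time on one side of the control mean. It added the 4 highest and 4 lowest in early against late, up to 4 members of each programme list with the smallest p, and the 5 highest and 5 lowest in monocyte-derived cells. Genes named Gm or Rik were skipped, and genes under 0.1 of their level in another deposited type were named as open to free RNA, which could not be tested in RPE. For the MC21 pair it named the 10 highest and 10 lowest ratios per type at 50 CPM or more with intervals apart. Gpnmb in T cells was singled out from these after its values were seen. Gene positions are from a GRCm38 annotation.

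Alternatives were DESeq2 1.42.0, RLE scaling, no filter on genes, 20 or 200 cells as minimum, summed channels, the replicate number as a block, no strain term, C57BL/6J libraries alone, GLAST libraries alone, genes at 0.1 or more of their highest type, other denominators and minimums for shares, and each library left out in turn. The steps were tested on simulated data with 200 changed genes per contrast. Of 4-fold and 2-fold changes the test recovered 69% and 21% in microglia at 12 h, 65% and 17% at 4 d and 66% and 33% at 1 week, 78% and 21% in astrocytes at 12 h and 77% and 41% at 1 week, 90% and 42% in Müller glia at 4 d and 89% and 52% at 1 week, 92% and 73% in RPE at 12 h and 94% and 79% at 2 d, and 47% and 4% in monocyte-derived cells. False calls made up 1.1% to 7.3%, which need not hold for the real libraries. For contrasts of at least 3 libraries per group other splits were tested. At first 35 were drawn in microglia and astrocytes and 30 in Müller glia, raised to 100 and 45 after those counts were seen.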

Results

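Single-cell RNA sequencing counted transcripts of sorted immune cells and glia of the mouse retina before and after optic nerve crush, an injury that cuts the axons of the retinal ganglion cells (RGCs) behind the eye. A second tissue, the eyecup left after removal of the retina, was sorted for the retinal pigment epithelium (RPE), the pigmented layer that nourishes the photoreceptors, and for CD45. Its barcodes were all taken as RPE, so immune cells may be among them. The retina table held 121309 cells in 33 libraries: 8 of uninjured controls, 3 at 12 h, 4 at 1 d, 4 at 2 d, 3 at 4 d, 5 at 1 week and 6 at 2 weeks after the crush. These libraries held 386 to 7465 cells and 1557733 to 45969936 transcript counts (UMIs) each, with a median of 2042 to 7231 UMIs per cell. The eyecup table held 6 libraries (1 control, 2 at 12 h, 1 at 1 d and 2 at 2 d) of 631 to 2605 cells and 12748524 to 42555680 UMIs each. A further pair of libraries at 7 d, 1 from retina treated with the antibody MC21, which depletes monocytes through CCR2, and 1 without it, held 2810 and 4633 cells and 28419624 and 47290339 UMIs. Counts were summed per library and deposited cell type, so the library is the replicate. The labels do not name separate animals, so p-values measure only the spread between these libraries, which may be technical.

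The first question was how microglia, the resident macrophages of the retina, change with time after the crush. At 12 h (2 libraries against 4 controls) genes of resting microglia were lower and inflammatory genes higher. P2ry12 (chromosome 3, 59216272 to 59262871), the receptor by which microglia sense released nucleotides, was at 252 ± 50.3 CPM against 1540 ± 220 CPM in controls (SD), a log2 fold change of -2.61 ± 0.23 (SE). Values in parentheses after a gene are log2 fold changes ± SE from edgeR's quasi-likelihood test, and each gene said to have risen or fallen had a Benjamini-Hochberg adjusted p under 0.05. Slc2a5 (-3.27 ± 0.26), Gpr34 (-2.97 ± 0.21) and Selplg (-1.84 ± 0.20) also fell. In the homeostatic list, 12 of 21 genes fell (15 over the list alone, adjusted p = 0.0139 at estimated correlation). Counts over the list alone are of p adjusted over its genes, and p for lists is camera's. Il1b (4.01 ± 0.47) rose to 514 ± 200 CPM from 33.1 ± 10.5, together with the chemokine gene Ccl12 (3.06 ± 0.29), the prostaglandin synthase gene Ptgs2 (2.22 ± 0.63) and the co-receptor gene Cd14 (0.90 ± 0.17). Of the list of inflammatory cytokines and chemokines, 10 of 20 genes rose (14 over the list alone, adjusted p = 0.0104 at estimated correlation). Slc39a14 (3.10 ± 0.40) and Srgn (1.59 ± 0.23) rose as well, and Tgm1 (5.79 ± 0.49 CPM against 0.102 ± 0.204). For some called genes the level in microglia was under 0.1 of that in another deposited type, so that RNA released from those cells could supply it, and such genes are named here as open to free RNA. Among these, Il1rn (5.73 ± 0.34) rose and Glul (-1.77 ± 0.28) fell at 12 h, and Timp1 rose to 7.07 ± 0.681 CPM from 0.0509 ± 0.102. Beside them 3 of the 5 measured neutrophil markers rose and 1 fell (camera adjusted p = 0.258 at estimated correlation). At 1 d (3 libraries) the glycolysis gene Gapdh (1.04 ± 0.24) rose and the iron exporter gene Slc40a1 (-0.97 ± 0.25) fell, and 7 of 21 (9 over the list alone, adjusted p = 0.0661 at estimated correlation) homeostatic genes were below control. The call of Ptgs2 ended without 12 h replicate 1 (1.78) or control replicate 4 (2.03) or 5 (2.06), and that of Slc40a1 without 1 d replicate 3 (-0.70).

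At 2 d (3 libraries) and 4 d (2 libraries) the genes of dividing cells stood out. Birc5 (3.70 ± 0.39) (chromosome 11, 117849251 to 117855743) and Cenpf (4.50 ± 0.49), which act in chromosome segregation, rose at 2 d, when of the cell cycle list 19 of 25 genes rose (24 over the list alone, adjusted p = 0.0104 at estimated correlation). At 4 d 22 of 25 (22 over the list alone, adjusted p = 0.0152 at estimated correlation) rose, with Pclaf (4.25 ± 0.44), Tk1 (3.66 ± 0.30), Cdk1 (3.64 ± 0.45), Ube2c (3.55 ± 0.46) and Tyms (2.72 ± 0.28). At 1 d the same list had 7 members up (adjusted p = 0.559 at estimated correlation), and at 2 weeks 11 of 25 genes fell (17 over the list alone, adjusted p = 0.144 at estimated correlation). Of the disease-associated list, genes that microglia raise around damaged tissue, 13 of 22 genes rose (17 over the list alone, adjusted p = 0.12 at estimated correlation) at 4 d. Spp1 (4.49 ± 0.62) (chromosome 5, 104435118 to 104441050), which encodes osteopontin, was at 748 ± 140 CPM against 32.1 ± 17, and the lipase gene Lpl (2.82 ± 0.25) rose too. Ldha (1.33 ± 0.26) and Slc16a3 (1.98 ± 0.27), which make and export lactate, and the chemokine gene Cxcl10 (1.77 ± 0.33) rose with them. Genes of the immediate early response, which tissue dissociation can raise too, fell: Atf3 (-1.29 ± 0.20), Jun (-1.38 ± 0.35), Klf4 (-1.88 ± 0.37), Klf6 (-0.93 ± 0.21) and, at 2 d, Dusp1 (-1.49 ± 0.32). Of the list of immediate early and dissociation stress genes 11 of 22 genes fell (14 over the list alone, adjusted p = 0.137 at estimated correlation). In the AP-1 and ATF list, 3 of 17 genes fell (5 over the list alone, adjusted p = 0.158 at estimated correlation). The highest fold changes at 4 d included genes of astrocytes that are open to free RNA, Lcn2 (7.27 ± 1.25), Serpina3n (5.21 ± 0.96) and Chil1 (3.54 ± 0.77). The lowest included genes of neurons, Vsnl1 (-3.82 ± 0.98), Calb2 (-3.37 ± 1.06) and Snap25 (-3.01 ± 0.77), which are open to it too. Of the RGC markers, 3 of 13 genes fell (8 over the list alone, adjusted p = 0.412 at estimated correlation). In the monocyte and macrophage markers, 5 of 7 genes rose (5 over the list alone, adjusted p = 0.202 at estimated correlation). Without 4 d replicate 1, the only C57BL/6J library of that time, the calls of Lcn2 (3.15), Serpina3n (4.34), Chil1 (1.40), Vsnl1 (-2.77), Calb2 (-2.35), Snap25 (-2.17), Jun (-1.75), Klf4 (-1.59), Klf6 (-0.76) and Ldha (1.09) ended. So did those of Jun without 4 d replicate 3 (-1.07), Calb2 without control replicate 4 (-3.10) or 8 (-3.06), and Dusp1 without 2 d replicate 4 (-1.42).

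At 1 and 2 weeks (4 and 5 libraries) disease-associated, interferon-induced and antigen presentation genes of microglia were above control, and interferon-induced ones already at 4 d. Cst7 (3.75 ± 0.22) (chromosome 2, 150570415 to 150578944), an inhibitor of cysteine proteases, was at 320 ± 37 CPM against 23.9 ± 5.01 at 1 week, and the growth factor genes Igf1 (2.61 ± 0.50) and Csf1 (1.09 ± 0.26) rose. Of the disease-associated list 14 of 22 genes rose (17 over the list alone, adjusted p = 0.0289 at estimated correlation) at 1 week and 10 of 22 (14 over the list alone, adjusted p = 0.0572 at estimated correlation) at 2 weeks. Of the interferon response list 23 of 38 genes rose (31 over the list alone, adjusted p = 0.209 at estimated correlation) at 4 d. At 1 week 24 of 38 (32 over the list alone, adjusted p = 0.12 at estimated correlation) and at 2 weeks 22 of 38 (34 over the list alone, adjusted p = 0.14 at estimated correlation) did, and at 2 d 6 of 38 (21 over the list alone, adjusted p = 0.296 at estimated correlation). Ifitm3 (2.51 ± 0.25), which blocks the entry of viruses, and Lgals3bp (2.65 ± 0.23) were among those of 1 week. Of the genes of antigen presentation by MHC class I, 9 of 12 genes rose (10 over the list alone, adjusted p = 0.0455 at estimated correlation) at 1 week. The complement genes C2 (2.99 ± 0.45) and C4b (3.17 ± 0.57) rose. In the complement list, 5 of 13 genes rose (6 over the list alone, adjusted p = 0.0855 at estimated correlation). Ccl5 (2.58 ± 0.32), a chemokine that draws T cells, and Egln3 (1.32 ± 0.31) rose at 2 weeks. The MHC class II genes H2-Aa (2.25 ± 0.41) and H2-Eb1 (2.22 ± 0.40) rose but are open to free RNA of dendritic cells and macrophages. Hmgcs1 (-1.77 ± 0.33), an early enzyme of cholesterol synthesis, fell. In the cholesterol list, 4 of 19 genes fell (9 over the list alone, adjusted p = 0.179 at estimated correlation). Genes of Müller glia and astrocytes fell at 2 weeks and are open to free RNA, such as Aldoc (-2.24 ± 0.43), Mt3 (-2.61 ± 0.33) and Sox9 (-2.69 ± 0.65). Of the astrocyte markers 3 of 8 genes fell (7 over the list alone, adjusted p = 0.258 at estimated correlation). In the RGC markers, 8 of 13 genes fell (11 over the list alone, adjusted p = 0.269 at estimated correlation). The calls of Csf1 without control replicate 8 (0.83), Egln3 without control replicate 4 (1.22), and Sox9 without control replicate 4 (-2.51) or 2 weeks replicate 1 (-2.73) or 2 (-2.35) ended.

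Early times (12 h to 2 d, 8 libraries) were then set against late times (4 d to 2 weeks, 11 libraries). The controls are not in this contrast but enter the fit of strain and spread. Apoe (-3.23 ± 0.33), a lipid carrier, Cfb (-4.24 ± 0.37), a complement factor, Itgax (-2.79 ± 0.16), Ank (-1.87 ± 0.17) and C3 (-2.06 ± 0.25) were lower early than late. Irf7 (-2.03 ± 0.19), Ifi27l2a (-2.49 ± 0.20), H2-D1 (-1.19 ± 0.14), H2-Q7 (-1.72 ± 0.20) and B2m (-1.12 ± 0.14) were lower early too. Of the interferon list 31 of 38 genes were lower early (33 over the list alone, adjusted p = 0.137 at estimated correlation). In the disease-associated list, 17 of 22 genes were lower early (18 over the list alone, adjusted p = 0.0455 at estimated correlation). In the MHC class I list, 11 of 12 genes were lower early (12 over the list alone, adjusted p = 0.0152 at estimated correlation). Genes of the cholesterol pathway were higher early, among them Fdps (1.04 ± 0.18), Mvd (0.78 ± 0.16) and Cyp51 (0.74 ± 0.16), and 9 of 19 genes were higher early (10 over the list alone, adjusted p = 0.144 at estimated correlation) of that list. Transcripts of RGCs, which are open to free RNA, were higher early: Calb2 (3.84 ± 0.58), Nrn1 (3.18 ± 0.53) and Sncg (2.82 ± 0.55), with 10 of 13 (11 over the list alone, adjusted p = 0.319 at estimated correlation) of the RGC markers. Their median was 2.08 ± 0.31 over 11 markers in microglia and 3.16 ± 0.46 over the same markers in monocyte-derived cells. Xist (-3.91 ± 0.81), a transcript of female cells, differed as well, and the labels give mixed sexes for some libraries and males for others. Its call ended without 1 d replicate 4 (-1.18) or 4 d replicate 3 (-3.38).

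**Figure D1:**
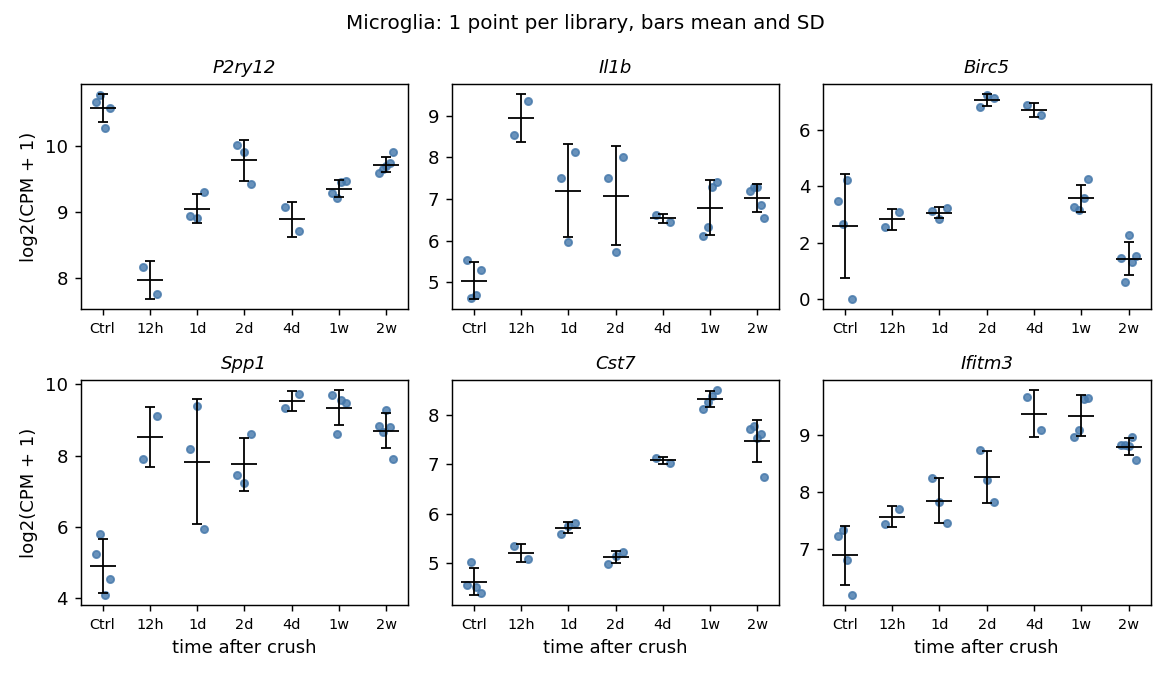
Level of 6 genes in microglia of each library, as log2(CPM + 1), against time after optic nerve crush, where points are libraries, and the line and bars give mean and SD. P2ry12 was lowest at 12 h (252 ± 50.3 CPM), Birc5 rose at 2 d, and Cst7 reached 320 ± 37 CPM at 1 week.

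In microglia edgeR called 868 genes higher and 784 lower at 12 h, 709 and 369 at 1 d, 386 and 92 at 2 d, 1061 and 666 at 4 d, 607 and 459 at 1 week, and 294 and 286 at 2 weeks, of 13531 genes tested. Early against late called 1101 higher and 1008 lower, 536 of them open to free RNA. DESeq2 split the 2 d calls into 540 higher and 251 lower. These numbers rest on few libraries: without 12 h replicate 1 or 2 there were 847 or 940 calls at 12 h, without 1 d replicate 2 there were 358 at 1 d, and without 4 d replicate 1 or 3 there were 387 or 985 at 4 d. The 2 d count became 318 without 2 d replicate 4, and 314, 798 and 297 without control replicates 5, 7 and 8. The 1 week count became 563 and 544 without 1 week replicates 4 and 5, and 671 and 620 without control replicates 4 and 8. At 2 weeks it became 332 and 224 without replicates 1 and 2 of that time, and 213 and 1136 without control replicates 4 and 7. Early against late became 1104 without 12 h replicate 2 and 898 without 4 d replicate 1. Within C57BL/6J libraries alone 783, 142, 137, 306, 69 and 278 genes were called from 12 h to 2 weeks, and 463 early against late. With libraries of a title summed there were 846, 417, 190, 844, 145 and 100, and 1067 early against late. Time and sequencing batch cannot be told apart. Libraries sorted for RGCs and immune cells shared lanes across times (2 control, 1 at 1 d, 1 at 2 d and 2 at 2 weeks), but a fit within them has its spread from the 2 libraries of 2 weeks alone, which share a title.

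Astrocytes, from gates with CD140a and from gates for RGCs and immune cells, were examined next to ask how the glia of the nerve fibre layer respond. At 12 h (2 libraries against 3 controls) genes of acute-phase and cytokine signalling were among those that rose. Lcn2 (chromosome 2, 32384633 to 32388252), which encodes the iron-binding lipocalin 2, was at 4470 ± 3170 CPM against 6.6 ± 5.13 (10.24 ± 1.61). Timp1 (8.85 ± 1.28), Steap4 (8.94 ± 1.10), Ptx3 (6.51 ± 0.85), Ifi203 (7.90 ± 0.59) and Cd44 (3.06 ± 0.24) rose. So did the cytokine and chemokine genes Lif (6.97 ± 0.58), Ccl7 (5.69 ± 0.47) and Ccl2 (4.84 ± 0.66). Tgm1, at 64.5 ± 38.5 CPM, and Csf3, at 96.5 ± 29 CPM, were close to 0 in controls (0.0579 ± 0.1 and 0.365 ± 0.559 CPM), so their fitted folds are not given. Cxcl2 (6.35 ± 0.83) rose but is open to free RNA of neutrophils. Of the neutrophil markers 3 of 6 genes rose (4 over the list alone, adjusted p = 0.318 at estimated correlation). Every gene of the pan-reactive list moved: 16 of 17 genes rose (16 over the list alone, adjusted p = 0.018 at estimated correlation) and 1 fell. Of the A2 list, genes raised in astrocytes after loss of blood flow, 7 of 10 genes rose (9 over the list alone, adjusted p = 0.0167 at estimated correlation). In the A1 list, 6 of 10 genes rose (6 over the list alone, adjusted p = 0.124 at estimated correlation). Mt2 (2.68 ± 0.29) and Mt1 (2.32 ± 0.27), which bind zinc and copper, rose, and 6 of 9 genes rose (7 over the list alone, adjusted p = 0.0293 at estimated correlation) of their list. Of the inflammatory list 10 of 19 genes rose (12 over the list alone, adjusted p = 0.0623 at estimated correlation). In the AP-1 and ATF list, 10 of 16 genes rose (11 over the list alone, adjusted p = 0.128 at estimated correlation), among them Fosl1 (4.52 ± 0.58). The growth factor gene Fgf2 (1.59 ± 0.24) rose and Fgf1 (-1.63 ± 0.19) fell, and in their list 9 rose and 4 fell of 21 (adjusted p = 0.287 at estimated correlation). Cyp26b1 (-3.63 ± 0.56), which degrades retinoic acid, Btbd17 (-3.26 ± 0.39), Gpr179 (-3.04 ± 0.20), Timp4 (-2.69 ± 0.23), Sned1 (-2.47 ± 0.31) and Cldn10 (-2.31 ± 0.36) fell. In the cholesterol list, 10 of 19 genes fell (15 over the list alone, adjusted p = 0.128 at estimated correlation).

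From 1 d to 4 d reactive genes of astrocytes stood above control. Of the pan-reactive list 7 of 17 genes rose (12 over the list alone, adjusted p = 0.038 at estimated correlation) at 1 d, and 6 of 17 (11 over the list alone, adjusted p = 0.0623 at estimated correlation) did at 2 d. At 4 d 12 of 17 (14 over the list alone, adjusted p = 0.0711 at estimated correlation) did. At 4 d (2 libraries) Gfap (2.16 ± 0.25) (chromosome 11, 102887336 to 102900912) and Vim (2.71 ± 0.30), filament genes of reactive glia, rose. C3 (chromosome 17, 57203970 to 57228136), the central complement gene, was at 91 ± 40.5 CPM against 0.174 ± 0.301, and Serping1 (3.52 ± 0.49) rose. Of the complement list 5 of 13 genes rose (5 over the list alone, adjusted p = 0.482 at estimated correlation). Glul (-2.49 ± 0.28), which turns glutamate into glutamine, Slc6a11 (-1.03 ± 0.17), which takes up GABA, and the glucose transporter gene Slc2a1 (-1.12 ± 0.18) fell. In the list of Müller glia functions, which astrocytes share in part, 1 member rose and 6 fell of 24 (adjusted p = 0.81 at estimated correlation); its median was positive (0.08) and its mean negative (-0.20). Birc5 (4.55 ± 0.91) rose at 2 d, whereas Ube2c (5.15 ± 1.14) did not pass, and 1 of 21 cell cycle genes rose at 2 d (12 over the list alone, adjusted p = 0.411 at estimated correlation). At 4 d 8 of 21 (9 over the list alone, adjusted p = 0.506 at estimated correlation) rose. Rgr (-3.34 ± 0.77), a gene of Müller glia and RPE, fell at 4 d and is open to free RNA. In the RGC markers, 5 of 13 genes fell (6 over the list alone, adjusted p = 0.569 at estimated correlation). The call of Birc5 ended without 2 d replicate 2 (2.27) or control replicate 4 (4.06), 5 (4.51) or 7 (4.87), and that of Rgr without 4 d replicate 1 (-2.75), while Ube2c passed without 12 h replicate 1 or 2 (5.17 each), 2 d replicate 3 (5.70) or 4 (5.44).

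At 1 and 2 weeks (4 libraries each) interferon-induced and antigen presentation genes were high and cholesterol synthesis genes low in astrocytes. H2-D1 (2.73 ± 0.25) (chromosome 17, 35262730 to 35267499), an MHC class I gene, was at 1470 ± 420 CPM against 209 ± 13.9, and H2-K1 (1.99 ± 0.23) rose. Of the interferon list 28 of 35 genes rose (31 over the list alone, adjusted p = 0.038 at estimated correlation) at 4 d, and 30 of 35 (32 over the list alone, adjusted p = 0.0167 at estimated correlation) did at 1 week. At 2 weeks 21 of 35 (26 over the list alone, adjusted p = 0.0167 at estimated correlation) did. Of the MHC class I list 9 of 12 genes rose (11 over the list alone, adjusted p = 0.0178 at estimated correlation) at 1 week, and 10 of 12 (10 over the list alone, adjusted p = 0.0935 at estimated correlation) did at 4 d. At 2 weeks 5 of 12 (8 over the list alone, adjusted p = 0.0293 at estimated correlation) did. Hmgcs1 (-1.64 ± 0.20) (chromosome 13, 119690379 to 119708260), Lss (-1.85 ± 0.20) and Sc5d (-1.34 ± 0.16), enzymes of cholesterol synthesis, fell, as did the iron uptake gene Tfrc (-1.58 ± 0.21). Of the cholesterol list 17 of 19 genes fell (19 over the list alone, adjusted p = 0.0167 at estimated correlation) at 1 week and 9 of 19 (18 over the list alone, adjusted p = 0.0167 at estimated correlation) at 2 weeks. Of the A1 list 6 of 10 genes rose (7 over the list alone, adjusted p = 0.0319 at estimated correlation) at 1 week and 6 of 10 (6 over the list alone, adjusted p = 0.0178 at estimated correlation) at 2 weeks. Ier2 (-0.78 ± 0.16) fell at 2 weeks with 4 of 22 (12 over the list alone, adjusted p = 0.0293 at estimated correlation) of the immediate early and dissociation stress list. Of the RGC markers 6 of 13 genes fell (10 over the list alone, adjusted p = 0.392 at estimated correlation) at 1 week. The call of Ier2 ended without 2 weeks replicate 2 (-0.72) or control replicate 4 (-0.69) or 7 (-0.74).

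Early against late (8 and 10 libraries), astrocytes differed in interferon, antigen presentation and cholesterol genes. Irf7 (-2.94 ± 0.12), Bst2 (-2.16 ± 0.15), H2-T23 (-1.71 ± 0.20), B2m (-1.40 ± 0.12), C4b (-1.23 ± 0.11) and Mdk (-0.85 ± 0.09) were lower early, as were Ifi27l2a (-4.27 ± 0.29) and Ly6e (-2.99 ± 0.28), which are open to free RNA. Of the interferon list 30 of 35 genes were lower early (31 over the list alone, adjusted p = 0.0178 at estimated correlation). In the MHC class I list, 7 of 12 genes were lower early (10 over the list alone, adjusted p = 0.038 at estimated correlation). Lcn2 (2.55 ± 0.69), Ier3 (1.29 ± 0.19), Pfkp (0.87 ± 0.14) and Atf4 (0.73 ± 0.11) were higher early. So were 5 of 10 (6 over the list alone, adjusted p = 0.0456 at estimated correlation) genes of the A2 list. In the cholesterol list 9 of 19 (15 over the list alone, adjusted p = 0.0801 at estimated correlation) were. Calb2 (3.58 ± 0.53), Sncg (2.92 ± 0.46) and Vsnl1 (2.92 ± 0.41) were higher early and are open to free RNA of RGCs. Of the RGC markers 11 of 13 (12 over the list alone, adjusted p = 0.256 at estimated correlation) were higher early. Of the microglia markers 4 of 10 genes were lower early (9 over the list alone, adjusted p = 0.622 at estimated correlation). Lcn2 differed between libraries of the late times: it was at 52.4 and 72.0 CPM in the C57BL/6J libraries at 1 week and at 2872 and 2522 CPM in those of the Vglut2-Cre cross, and at 2 weeks at 17.9 and 30.4 against 1831 and 2278 CPM. Strain, gate and sex differ together between these libraries, and no astrocyte control is of the cross. Xist (-3.92 ± 0.45) differed as in microglia. The calls of Xist without 1 d replicate 4 (-0.33) and of Lcn2 without 12 h replicate 2 (2.22) or 2 d replicate 4 (2.62) ended.

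**Figure D2:**
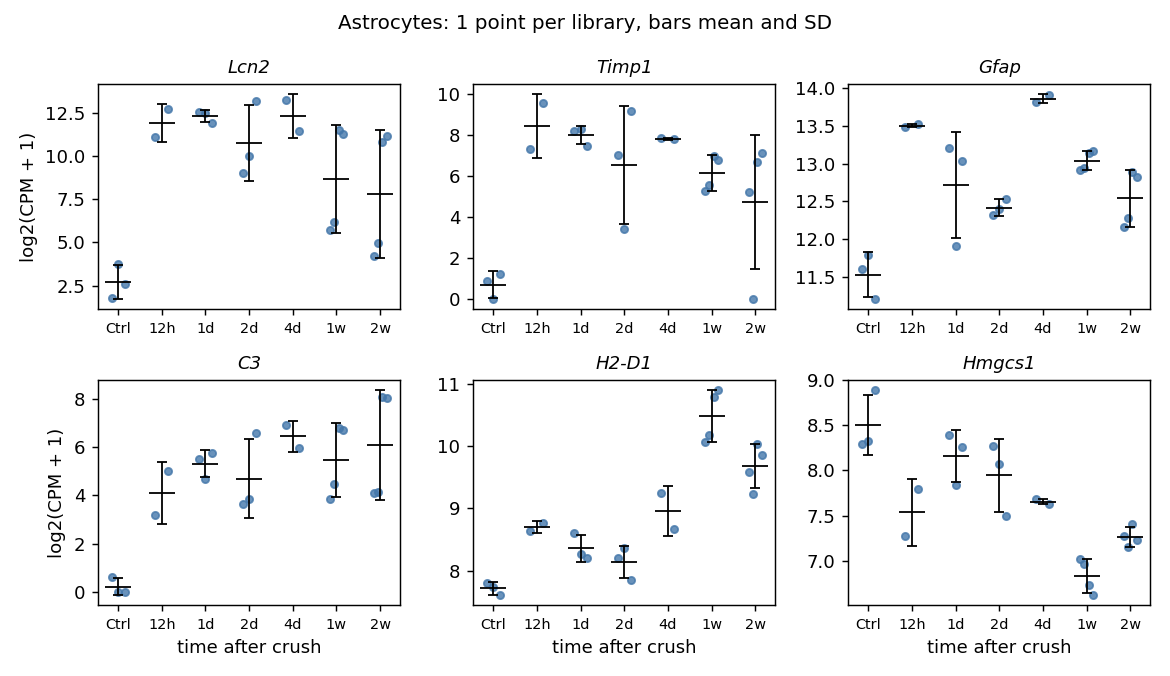
Level of 6 genes in astrocytes of each library, as log2(CPM + 1), against time after optic nerve crush, where points are libraries, and the line and bars give mean and SD. Lcn2 reached 4470 ± 3170 CPM at 12 h, C3 91 ± 40.5 CPM at 4 d, and Hmgcs1 fell by 1.64 on the log2 scale at 1 week.

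In astrocytes edgeR called 1089 genes higher and 1143 lower at 12 h, 232 and 82 at 1 d, 54 and 7 at 2 d, 979 and 879 at 4 d, 390 and 395 at 1 week, and 115 and 59 at 2 weeks, of 13890 tested. Early against late called 805 higher and 798 lower. DESeq2 split the 2 d calls into 192 higher and 76 lower. The 12 h count was 1399 without 12 h replicate 1 and 1414 without replicate 2. At 1 d it was 69 without 1 d replicate 2, and 1156, 192 and 106 without control replicates 4, 5 and 7. At 2 d it was 92 without 12 h replicate 1, 30 and 212 without 2 d replicates 2 and 3, and 123, 29 and 21 without control replicates 4, 5 and 7. At 4 d it was 285 without 4 d replicate 1 and 1191 without control replicate 7. At 1 week it was 442 and 419 without 1 week replicates 4 and 5, and 1241 and 434 without control replicates 4 and 7. At 2 weeks it was 115, 101, 108 and 99 without replicates 1, 2, 4 and 5 of that time, and 101 without control replicate 7. Early against late it was 791 without 12 h replicate 2, 1037 without 1 d replicate 4 and 633 without 4 d replicate 1. Within C57BL/6J libraries alone 1455, 107, 17, 736, 124 and 40 genes were called from 12 h to 2 weeks, and 311 early against late. With libraries of a title summed there were 52, 1, 957, 126 and 30 (30 higher) from 1 d to 2 weeks, and 799 early against late.

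Müller glia, the radial glia that span the retina, were compared in the same way, with the GLAST gate as a term in the model. At 12 h (2 libraries against 7 controls) Cebpb (3.63 ± 0.60) (chromosome 2, 167688915 to 167690418), a transcription factor of the acute-phase response, was at 756 ± 870 CPM against 49.5 ± 35.3. Stat3 (1.19 ± 0.18), Fosl1 (3.52 ± 0.51), Lif (2.78 ± 0.43), Clcf1 (1.47 ± 0.35), Fgf2 (1.76 ± 0.24), Ptx3 (2.41 ± 0.32), Ptgs2 (2.48 ± 0.52) and Tgm1 (6.46 ± 0.99) rose, as did the glucocorticoid-induced gene Fkbp5 (3.02 ± 0.39). The metal-binding genes Mt1 (2.30 ± 0.30), Mt2 (2.30 ± 0.32) and Mt3 (1.76 ± 0.25) and the zinc importer gene Slc39a14 (2.51 ± 0.34) rose, with 5 of 9 (5 over the list alone, adjusted p = 0.0752 at estimated correlation) of their list. Of the A2 list 7 of 9 genes rose (9 over the list alone, adjusted p = 0.0146 at estimated correlation). In the pan-reactive list, 11 of 16 genes rose (13 over the list alone, adjusted p = 0.124 at estimated correlation). In the inflammatory list, 7 of 19 genes rose (14 over the list alone, adjusted p = 0.256 at estimated correlation). The sterol-controlled genes Insig1 (-1.86 ± 0.32) and Fdft1 (-1.71 ± 0.32) fell. In the cholesterol list, 11 of 19 genes fell (16 over the list alone, adjusted p = 0.0375 at estimated correlation). Rlbp1 (-0.87 ± 0.23), which carries retinal in the visual cycle, and Cd59a (-1.07 ± 0.24) fell. mt-Co1 (1.60 ± 0.58), a mitochondrial gene, did not pass. At 1 d (3 libraries) Atf5 (1.89 ± 0.20) and Stmn1 (0.89 ± 0.30) rose and Vegfa (-1.66 ± 0.40), Egr2 (-1.61 ± 0.40) and Fosb (-1.21 ± 0.26) fell, while 11 of 35 interferon genes rose (12 over the list alone, adjusted p = 0.689 at estimated correlation). Without 12 h replicate 3, the GLAST library of that time, the calls of Cd59a (-0.90), Clcf1 (1.23), Fdft1 (-1.32), Fgf2 (1.32), Fosl1 (2.30), Insig1 (-1.67), Ptgs2 (2.71), Rlbp1 (-0.67), Slc39a14 (1.32) and Tgm1 (4.81) ended, and mt-Co1 passed (2.52). Without 12 h replicate 1 those of Cebpb (2.36), Mt3 (1.10) and Rlbp1 (-1.08) ended and mt-Co1 turned (-0.70). Without 1 d replicate 3 those of Egr2 (-1.30), Fosb (-0.95), Stmn1 (0.72) and Vegfa (-1.48) ended, and without 1 d replicate 1 those of Egr2 (-1.21) and Stmn1 (0.99).

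At 4 d (3 libraries) Vim (1.79 ± 0.15), S100a10 (2.00 ± 0.26), Crym (1.71 ± 0.20), Usp18 (2.91 ± 0.30) and Rtp4 (3.54 ± 0.37) rose, and so did the complement genes C4b (3.09 ± 0.31), Serping1 (2.35 ± 0.26) and C1ra (2.04 ± 0.32). Gfap (4.37 ± 0.55) rose too, at a level under 0.1 of that in astrocytes. Glul (-1.55 ± 0.24) (chromosome 1, 153899944 to 153909723) and Slc1a2 (-1.04 ± 0.20), which clear glutamate, fell, with Igf2 (-1.61 ± 0.45), Ddit4 (-1.27 ± 0.33) and mt-Co3 (-3.64 ± 1.19). In the list of Müller glia functions 3 members rose and 6 fell of 25 (adjusted p = 0.77 at estimated correlation). Of the interferon list 30 of 35 genes rose (34 over the list alone, adjusted p = 0.156 at estimated correlation). In the MHC class I list, 10 of 11 genes rose (11 over the list alone, adjusted p = 0.188 at estimated correlation). In the complement list, 8 of 12 genes rose (9 over the list alone, adjusted p = 0.446 at estimated correlation). In the pan-reactive list, 10 of 16 genes rose (11 over the list alone, adjusted p = 0.303 at estimated correlation). Of the disease-associated microglia list 15 of 21 genes rose (16 over the list alone, adjusted p = 0.303 at estimated correlation), among them Spp1 (3.91 ± 0.61) and beside Lyz2 (5.74 ± 0.99), which are open to free RNA of immune cells. Of the microglia markers 3 of 10 genes rose (4 over the list alone, adjusted p = 0.688 at estimated correlation). In the monocyte and macrophage markers, 3 of 3 genes rose (3 over the list alone, adjusted p = 0.608 at estimated correlation). Over 163 such immune transcripts the libraries without the GLAST gate, where immune cells made up 58.1% and 45.2% of cells, exceeded the GLAST library (5.86%) by a median log2 ratio of 0.87 ± 0.07. The calls of Ddit4 without 4 d replicate 3 (-1.01), Igf2 without replicate 1 (-1.44) or 2 (-1.51), and mt-Co3 without replicate 1 (-3.83), 2 (-3.81) or 3 (-3.27) ended.

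At 1 and 2 weeks (5 and 4 libraries) Gbp3 (2.44 ± 0.26) rose, and B2m (2.09 ± 0.26) and H2-D1 (1.88 ± 0.25) rose but are open to free RNA. Of the interferon list 24 of 35 genes rose (32 over the list alone, adjusted p = 0.124 at estimated correlation) at 1 week. At 2 weeks 14 of 35 (29 over the list alone, adjusted p = 0.0375 at estimated correlation) did. In the MHC class I list, 8 of 11 (11 over the list alone, adjusted p = 0.113 at estimated correlation) rose at 1 week. Of the cholesterol list 9 of 19 genes fell (16 over the list alone, adjusted p = 0.111 at estimated correlation) at 1 week and 1 of 19 (12 over the list alone, adjusted p = 0.0225 at estimated correlation) at 2 weeks. Early against late (9 and 12 libraries) Ifit1 (-2.32 ± 0.32), Rsad2 (-1.95 ± 0.43), Irf7 (-1.76 ± 0.24) and Isg15 (-1.63 ± 0.28) were lower early. In the interferon list 20 of 35 genes were lower early (29 over the list alone, adjusted p = 0.0375 at estimated correlation). In the MHC class I list 7 of 11 (11 over the list alone, adjusted p = 0.0729 at estimated correlation) did. Ednrb (1.11 ± 0.24), the endothelin receptor gene, and Far1 (0.72 ± 0.12) were higher early. Calb2 (2.75 ± 0.56) was higher early and is open to free RNA of RGCs, beside 2 of 11 (7 over the list alone, adjusted p = 0.262 at estimated correlation) RGC markers. Early against late, calls ended without 12 h replicate 3 for Calb2 (2.14), Ednrb (0.78), Isg15 (-1.54) and Rsad2 (-2.04). They also ended for Calb2 without 2 d replicate 4 (2.49), for Ednrb without 1 week replicate 1 (1.05), 2 d replicate 4 (0.92) or 4 d replicate 1 (1.00), and for Rsad2 without 12 h replicate 1 (-1.90), 1 d replicate 3 (-1.85), 1 week replicate 2 (-1.67) or 4 d replicate 2 (-1.64).

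In Müller glia edgeR called 483 genes higher and 286 lower at 12 h, 1312 and 1131 at 1 d, 15 and 0 at 2 d, 1373 and 1076 at 4 d, 307 and 262 at 1 week, and 36 and 4 at 2 weeks, of 13379 tested. The 0 lower at 2 d compare with 4 by DESeq2 and with 1121 genes in both directions at an unadjusted p under 0.05. Early against late called 26 higher and 69 lower. DESeq2 split the 12 h calls into 609 and 564, the 2 week calls into 73 and 19, and early against late into 67 and 111. The median of all genes at 1 d lay at -0.14, and at -0.10 under RLE and -0.11 under DESeq2 scaling, so changes at 1 d are relative to that shift. The 12 h count was 389 without 12 h replicate 1 and 141 without replicate 3, and that of 1 d was 946 and 1103 without 1 d replicates 1 and 3. At 2 d edgeR called 0 genes without 12 h replicate 1, 1 week replicate 2, 3, 4 or 5, 2 d replicate 2 or 4, or 2 weeks replicate 4, with 1217, 1071, 1083, 1106, 1097, 1803, 861 and 1081 genes at an unadjusted p under 0.05. It called 23 without 2 d replicate 1, 3 and 28 without 2 weeks replicates 5 and 6, and 8 without 4 d replicate 1. The 4 d count was 1048 and 772 without 4 d replicates 1 and 2, and that of 1 week was 142, 298 and 277 without 1 week replicates 1, 2 and 3. At 2 weeks it was 15 and 17 without replicates 4 and 5 of that time, and early against late it was 19 without 12 h replicate 3. With libraries of a title summed there were 0 at 2 d (1053 at an unadjusted p under 0.05), 210 at 1 week, 9 at 2 weeks and 54 early against late.

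**Figure D3:**
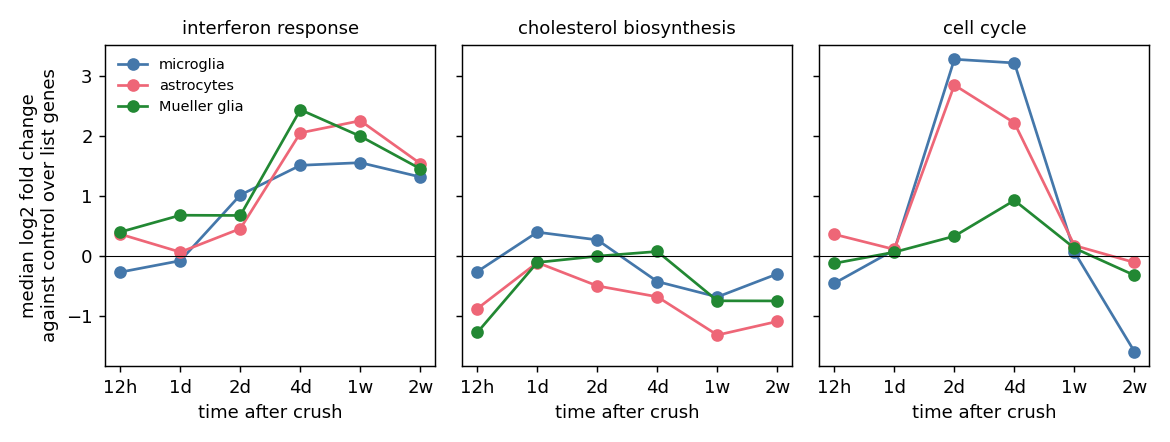
Median log2 fold change against control over the members of the interferon response, cholesterol biosynthesis and cell cycle lists, against time after optic nerve crush, in microglia, astrocytes and Müller glia (lines). In astrocytes the interferon median was 2.26 and the cholesterol median -1.32 at 1 week, and in microglia the cell cycle median was 3.29 at 2 d.

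Whether the interferon response differed between microglia and astrocytes of the same libraries was tested as the difference of their mean log2 CPM over the list. At 1 week the interferon score rose by 1.39 in microglia and 1.87 in astrocytes (4 libraries against 3 controls, difference -0.49, two-sided exact permutation p = 0.0286, the smallest that this design allows). After Benjamini-Hochberg adjustment over lists and times this was 0.343, and no list passed at any time, while 10 comparisons had an unadjusted exact p of 0.0286. The difference was -0.51 at 12 h, -0.13 at 1 d, 0.42 at 2 d, -0.42 at 4 d and -0.20 at 2 weeks, with exact p from 0.1 to 0.4. The pan-reactive list, which holds Lcn2, Gfap and Vim, differed by -1.22 at 1 week and -1.41 at 2 weeks, higher in astrocytes, and the A1 list by -0.91 and -0.82. Cholesterol genes fell by 0.66 in microglia and by 1.48 in astrocytes at 1 week (difference 0.82), and differed by 0.69 at 2 weeks. Cell cycle genes differed by -0.91 and metallothioneins by -0.45 at 2 weeks, and mitochondrial genes by 0.85 at 1 week.

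The eyecup libraries asked whether the RPE responds. At 12 h (2 libraries against 1 control) Serpina3n (7.66 ± 0.09) (chromosome 12, 104406729 to 104414329), an acute-phase protease inhibitor, was at 164 ± 0.811 CPM against 0.806 in the control. Il34 (6.21 ± 0.36), Tnfrsf12a (5.98 ± 0.08), Plat (5.65 ± 0.09), Krt16 (4.65 ± 0.09), Ptx3 (4.91 ± 0.28) and Fabp5 (4.40 ± 0.14) rose, and Lcn2 and Sphk1 rose from 0.101 and 0.0756 CPM to 35.3 ± 2.81 and 34.6 ± 2.9 CPM. Interferon genes rose early and fell by 2 d: Ifit1 (5.00 ± 0.09) rose at 12 h and fell (-4.63 ± 0.08) from 12 h to 2 d, with Iigp1 (-6.09 ± 0.24), Ifit3 (-2.94 ± 0.05) and Cxcl10 (-4.49 ± 0.15). Of the interferon list 36 of 38 genes rose (36 over the list alone, adjusted p = 0.375 at estimated correlation) at 12 h. At 2 d 17 of 38 (21 over the list alone, adjusted p = 0.418 at estimated correlation) did. At 2 d against 12 h 33 of 38 (34 over the list alone, adjusted p = 0.375 at estimated correlation) of these fell. Of MHC class I 11 of 12 genes rose (11 over the list alone, adjusted p = 0.375 at estimated correlation), with H2-Q4 (4.12 ± 0.19), Psmb8 (3.02 ± 0.18) and Tap1 (2.87 ± 0.16). Of the pan-reactive list 15 of 15 genes rose (15 over the list alone, adjusted p = 0.375 at estimated correlation). In the inflammatory list, 17 of 20 rose (17 over the list alone, adjusted p = 0.418 at estimated correlation), with Il1b (5.64 ± 0.22) and Cxcl2 (3.77 ± 0.08), both open to RNA of neutrophils. Of the cholesterol list 15 of 19 genes rose (15 over the list alone, adjusted p = 0.375 at estimated correlation) at 12 h. From 12 h to 2 d 16 of 19 (16 over the list alone, adjusted p = 0.375 at estimated correlation) fell, among them Idi1 (-3.67 ± 0.12), Hmgcs1 (-1.22 ± 0.04) and Cyp51 (-1.11 ± 0.04).

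Some genes of RPE function were lower at 12 h and less so at 2 d. Rgr (-0.84 ± 0.02), a retinal-binding opsin, Rlbp1 (-0.95 ± 0.03), Prcd (-1.79 ± 0.04), Sostdc1 (-1.66 ± 0.04) and Dapl1 (-1.55 ± 0.04) were lower at 12 h. Of the visual cycle and pigment list 5 rose and 11 fell of 21 at 12 h (adjusted p = 0.469 at estimated correlation), with a median of -0.18, a mean of 0.04 and a lower level by camera. At 2 d 13 of them fell, and Rgr was at -0.29 ± 0.02, Rlbp1 at -0.24 ± 0.03, Prcd at -0.28 ± 0.03, Sostdc1 at -1.09 ± 0.03 and Dapl1 at -0.29 ± 0.04. Of the RPE markers 6 of 8 genes fell (6 over the list alone, adjusted p = 0.418 at estimated correlation). The neutrophil genes S100a8 (9.64 ± 0.16) (chromosome 3, 90668978 to 90670035) and S100a9 (9.07 ± 0.13) rose, with 8 of 8 (8 over the list alone, adjusted p = 0.423 at estimated correlation) neutrophil markers. S100a8 gave a UMI in 88.5% and 90.1% of barcodes at 12 h, 57.7% at 1 d, 40.7% and 42.2% at 2 d and 0.614% in the control. Thinned to 5000 UMIs per barcode, these shares were 66.8% and 70.7%, 23.1%, 14.8% and 14.7%, and 0.0799%. Ptprc, a gene of immune cells, gave a UMI in 3.24% and 3.4% of barcodes at 12 h, 3.96% at 1 d, 3.55% and 3.0% at 2 d and 0.422% in the control. At 2 d against 12 h genes of macrophages and microglia rose, C1qc (3.61 ± 0.18), C1qb (3.46 ± 0.13), C1qa (3.19 ± 0.16) and Cd74 (3.07 ± 0.19), beside 6 of 7 (7 over the list alone, adjusted p = 0.459 at estimated correlation) of the microglia markers. At 2 d 10 of 10 (10 over the list alone, adjusted p = 0.375 at estimated correlation) of the monocyte and macrophage markers were above control. Of the MHC class II list 5 of 7 (5 over the list alone, adjusted p = 0.65 at estimated correlation) fell at 12 h. Of the same list 7 of 7 (7 over the list alone, adjusted p = 0.438 at estimated correlation) rose from 12 h to 2 d. Cell cycle genes such as Rrm2 (3.28 ± 0.24) rose to 2 d, when 19 of 25 (19 over the list alone, adjusted p = 0.375 at estimated correlation) of their list were above control. Hmox1 (-3.66 ± 0.06), Fkbp5 (-3.88 ± 0.20) and Fgf2 (-3.17 ± 0.22) fell from 12 h to 2 d.

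**Figure D4:**
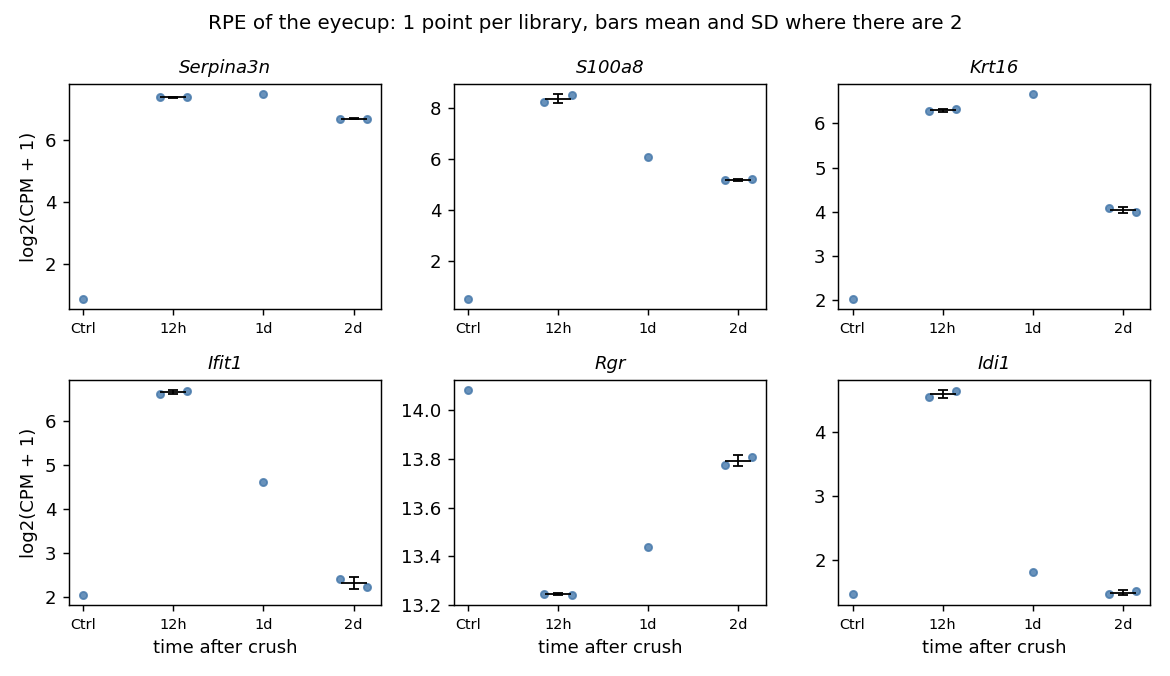
Level of 6 genes in RPE of each eyecup library, as log2(CPM + 1), against time after optic nerve crush, where points are libraries, and the line and bars give mean and SD where a time has more than 1 library. Serpina3n was at 164 ± 0.811 CPM at 12 h, and Idi1 fell by 3.67 on the log2 scale from 12 h to 2 d.

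In RPE edgeR called 5451 genes higher and 4440 lower at 12 h, 2571 and 2213 at 1 d, 2275 and 1644 at 2 d, and 4697 and 4974 at 2 d against 12 h, of 15717 tested. The control and 1 d have 1 library each, assumed to vary like the libraries of 12 h and 2 d, and the fit has 2 residual degrees of freedom. The 1 d counts thus compare 1 library with 1 and have no replicate check. The paired libraries of 12 h and of 2 d share their title and may be repeat channels of a sample, so these counts overstate what separate eyes would show. DESeq2 split the 12 h calls into 2580 higher and 3257 lower, and RLE scaling split those of 1 d into 2289 and 2707 and those of 2 d into 1944 and 2316. The median of all genes at 12 h lay at 0.10, and at 0.03 under RLE and DESeq2 scaling, so changes at 12 h are relative to that shift.

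Monocytes and macrophages (named monocyte-derived, origin not tested) were followed from 1 d to 1 week (2 libraries each). The 1 d libraries are C57BL/6J, and those of 1 week are of the Vglut2-Cre cross and share a title, so they may be 1 sample, and strain differs with time. Monocytes that carry Ly6C and Chil3 made up 53.1% and 13.8% of these cells at 1 d and 2.12% and 0.888% at 1 week, so changes of make-up and of expression are not separated. Arg1 (chromosome 10, 24915221 to 24927484), an enzyme of wound macrophages, was at 1.1 ± 0.411 CPM at 1 week against 659 ± 383 at 1 d (-10.29 ± 1.68). Chil3 (-6.50 ± 1.51), Prtn3 (-6.92 ± 1.10), F10 (-6.58 ± 0.84) and Hp (-6.51 ± 1.43), genes of young monocytes, fell, while Lag3 (5.07 ± 0.84), Cst7 (4.99 ± 0.86), Cd34 (4.78 ± 0.80), Rn7sk (4.90 ± 0.92) and Col27a1 (4.47 ± 0.78) rose. Genes listed for resting microglia were higher at 1 week: 17 of 21 genes rose (19 over the list alone, adjusted p = 0.289 at estimated correlation). In the microglia markers, 8 of 10 genes rose (10 over the list alone, adjusted p = 0.289 at estimated correlation). Of the disease-associated list 9 of 22 genes rose (12 over the list alone, adjusted p = 0.31 at estimated correlation). In the MHC class I list, 7 of 12 genes rose (8 over the list alone, adjusted p = 0.304 at estimated correlation). Of the monocyte and macrophage markers 7 of 12 genes fell (9 over the list alone, adjusted p = 0.289 at estimated correlation). In the glycolysis list, 7 of 18 genes fell (10 over the list alone, adjusted p = 0.33 at estimated correlation). In the RGC markers, 9 of 11 genes fell (10 over the list alone, adjusted p = 0.322 at estimated correlation). edgeR called 616 genes higher and 709 lower of 9526, 280 of them open to free RNA. Without 1 d replicate 2 it called 708, and without 1 week replicate 4 or 5 it called 323 or 451. The call of Chil3 ended without each of these (-4.68, -6.87 and -6.21), and that of Hp without 1 week replicate 5 (-6.07). Among B cells edgeR called 81 genes higher and 7 lower at 2 d and 533 and 361 at 2 weeks, of 3487. In amacrine cells it called 0 of 10677 at 1 d and 0 at 2 d, with 112 and 617 at an unadjusted p under 0.05, and no other tool was run.

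The share of each type among immune cells was compared per library. Monocytes and macrophages made up 11.1% ± 1.98 (SD, n = 4) at 1 week against 5.48% ± 2.13 (n = 4) in controls, above the control mean in 4 of 4 libraries (two-sided exact permutation p = 0.0286, the smallest possible). Neutrophils made up 12.0% ± 1.47 (n = 2) at 12 h against 3.73% ± 3.66 (exact p = 0.133, smallest possible 0.0667), and dendritic cells 3.67% ± 2.46 (n = 3) at 1 d against 0.0707% (exact p = 0.0286). T and NK cells made up 5.86% ± 2.00 (n = 5) at 2 weeks against 2.91% ± 1.91 (exact p = 0.0794), B cells 1.27% at 1 week against 6.46% (exact p = 0.0857), and microglia 71.2% ± 11.3 at 1 d against 80.8% ± 9.79 (exact p = 0.286). Patrolling monocytes marked by Ear2 made up 1.47% at 1 d against 0.410% (exact p = 0.0571). By the exact test 4 of the 42 comparisons had an unadjusted p under 0.05, and 0 passed adjustment (smallest adjusted p 0.3). Shares of deposited states within a type were also compared, and none passed adjustment (smallest adjusted p 0.367). Cycling cells made up 10.5% ± 1.56 of microglia, the low-UMI class included, at 2 d (n = 3) and 7.19% ± 0.362 at 4 d (n = 2) against 0.631% ± 0.551 in controls (exact p = 0.0286 at 2 d). Without that class, chosen after the data had been seen, they made up 15.2% ± 1.15, 13.8% ± 1.21 and 1.01% ± 0.965 (exact p = 0.0286 at 2 d). Reactive cells made up 29.3% ± 13.5 of astrocytes at 12 h and 19.7% ± 7.02 at 1 d against 1.58% ± 2.05. Cells of the Igf2 state made up 18.3% ± 4.04 of astrocytes at 2 weeks against 50.7% ± 15.3. Monocytes that carry Ly6C and Chil3 made up 45.6% ± 13.9 of monocytes and macrophages at 12 h and 33.5% at 1 d against 3.36% in controls, and 1.52% at 4 d.

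The MC21 pair asked which cells of the injured retina depend on blood monocytes. With 1 library per arm there is no test, and the exact binomial and Poisson 95% intervals cover counting error only. Macrophages marked by Gpnmb (chromosome 6, 49036546 to 49070929) were 9 of 2789 immune cells with MC21 (0.323%, 0.148 to 0.612) against 971 of 4625 without it (21%, 19.8 to 22.2). All monocytes and macrophages made up 3.76% (3.09 to 4.54) against 34.1% (32.8 to 35.5). Macrophages marked by Ms4a7 with low MHC class II made up 1.97% (1.49 to 2.56) against 11.1% (10.2 to 12.0), and those with high MHC class II 1.15% against 1.47%. Monocytes marked by Chil3 were 0 of 2789, which allows up to 0.108%, against 5 of 4625. Microglia made up 93.3% against 63.9%, and those of the interferon state 16.9% (15.5 to 18.4) against 3.85% (3.31 to 4.44). In microglia Gpnmb was at 16.2 CPM (14.7 to 17.8) with MC21 and 555 CPM (544 to 566) without it, and Igf1, Ms4a7, Fabp5 and Cxcl2 were lower by log2 ratios of -3.09, -2.88, -2.06 and -2.22. T cells (32 and 34 cells) showed the same: Gpnmb was at 15.8 CPM (5.81 to 34.5) with MC21 and 1050 CPM (940 to 1160) without it, above its level in microglia, so the microglial difference is open to free RNA of the Gpnmb macrophages. So are those of Igf1 (-3.1 in T cells, 0 against 604 CPM in neutrophils) and Fabp5 (-4.79 in neutrophils, 15 cells in each library). Qpct (89.7 against 16.5 CPM, log2 ratio 2.44), H2-T23 (1.11) and Myc (1.10) were higher with MC21 in microglia, but Qpct also in T cells (3.86) and Ms4a7 macrophages (2.84). In Ms4a7 macrophages (87 and 580 cells, 32 and 68 with high MHC class II) Lyve1 (5.89 from 6 UMIs without MC21, 3.96 thinned), Pf4 (3.14), Mrc1 (2.59) and Mmp12 (3.74) were higher with MC21. Gpnmb (-6.08) and Fabp5 (-3.67), open to free RNA too, and Acp5 (-3.8) were lower. In microglia 32 of 38 interferon genes and 11 of 12 MHC class I genes were higher with MC21. Their medians, 0.37 and 0.55, lay at percentile 100 of 10000 random lists of like expression, that of homeostatic genes (0.17) at 98.1, and those of cell cycle (-0.41) and disease-associated genes (-0.35) at 0. The last is open to free RNA too, as Spp1 was lower in T cells (-3.94) and Lpl in neutrophils (-4.09). The deposited cycling class of microglia was not lower: 1.72% (1.27 to 2.28) of immune cells with MC21 against 0.886% (0.637 to 1.2).

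**Figure D5:**
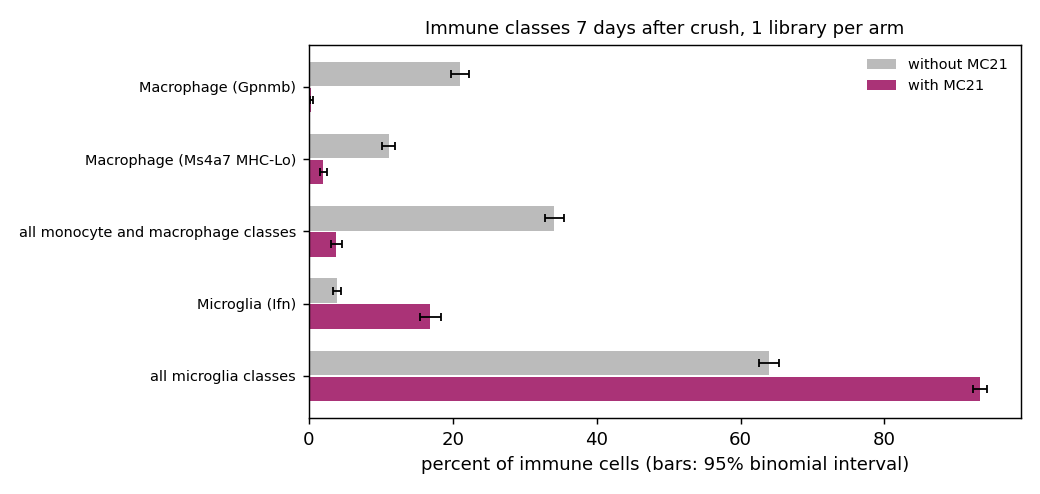
Share of immune cells (percent) in deposited classes at 7 d after the crush, with MC21 and without it (1 library each, bars), with exact binomial 95% intervals. Gpnmb macrophages were at 0.323% with MC21 and 21% without it, and interferon-state microglia at 16.9% and 3.85%.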

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

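The tests of ganglion cell transcripts were chosen after the result was seen, as were the first and last of the 3 tests of immune cells among RPE barcodes, the redrawn splits and those of summed titles. Of 198 groups of 4 to 10 libraries checked, 13 had a library apart from the others by Dixon's ratio, where chance gives about 1 in 20 (5%). In control microglia Tgm1 (ratio 1.0, 0.407 CPM in replicate 4 against 0), Timp1 (1.0, 0.204 against 0 in the same library), Slc40a1 (0.847, 15.3 against 28.7 in replicate 5), Lgals3bp (0.861, 115 against 178 in replicate 7), Lpl (0.848, 16 against 64.1 in replicate 8) and Tyms (0.956, 6.02 against 11.3 in replicate 8) stood apart. In microglia at 2 weeks Ccl5 (0.746, 683 against 1024 CPM in replicate 6) and H2-Aa (0.738, 32.7 against 55.2 in replicate 4) did. In control Müller glia Cd59a (0.878, 9.18 against 23.9 CPM in replicate 3), Lif (0.577, 12.9 against 2.65 in replicate 4), Tm4sf1 (0.791, 5.15 against 0.140 in replicate 4), Slc39a14 (0.670, 0 against 3.56 in replicate 8) and Rtp4 (0.807, 0 against 5.02 in replicate 8) did.

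In 9 of 120 comparisons of a list at a time every microglia library moved one way and every Müller glia library the other, where 4.8 are expected if each library took a side at random and none held both types, which part of them do. The difference was not tested, and genes of the other type are open to free RNA. Homeostatic microglia genes changed by -1.15 in microglia and 0.65 in Müller glia at 12 h (difference -1.80) and by -0.49 and 1.14 at 4 d (-1.64). MHC class I genes changed by -0.40 and 0.42 at 12 h (-0.82) and by -0.34 and 0.30 at 1 d (-0.63). AP-1 and ATF genes changed by -0.26 and 0.31 at 4 d (-0.57), genes of Müller glia function by 0.37 (-0.0285 with 3 of the 4 controls) and -0.19 at 4 d (0.56), and cholesterol genes by 0.36 and -0.14 at 2 d (0.50). Glycolysis genes changed by 0.11 and -0.23 at 1 d (0.34) and by 0.08 and -0.16 at 4 d (0.24).

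Transcripts of RGCs were higher early than late in microglia. With a term for RGC gates their median over 13 markers was 1.65 ± 0.26 (2.25 ± 0.30 without). The term cannot exclude sorted RGCs, as 1 d replicate 2, outside those gates, held 760. Free RNA may be a source: in monocyte-derived cells, which do not make these transcripts, the median was 3.16 ± 0.46 against 2.08 ± 0.31 in microglia over the same 11 genes. Uptake of RGC debris stays open and untested.

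Neutrophil transcripts rose in RPE barcodes at 12 h. Of RNA or cells of neutrophils, S100a8 and S100a9 would need a share that the other 6 markers need 0.705 and 0.712 times in the 12 h libraries, which is consistent with neutrophil RNA as a source. Whether neutrophils, which a gate for RPE and CD45 takes in, were sorted among the RPE was tested 3 times. Barcodes with more than 5 UMIs of S100a8 were 5.10 and 6.83 times as many as those with a UMI of Ptprc, a weak test as Ptprc is a low transcript. Their Rpe65 UMIs were 2.00 and 2.12 times those of other barcodes, a void test as they are deeper. Their Rpe65 per UMI, tested last, was 0.968 and 1.02 times that of others, which argues against barcodes of neutrophils alone. Expression of S100a8 by RPE itself stays open, as do neutrophils attached to RPE cells.

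Immune transcripts rose in Müller glia at 4 d. They were not brought by the deposited interferon class, since without it the median over 160 genes was 2.64 ± 0.09 against 2.79 ± 0.09. Free RNA of immune cells may contribute: the libraries without the GLAST gate exceeded the GLAST library by 0.87 ± 0.07 (log2) over 163 genes. The gate, the batch and the share of immune cells differ together between these libraries, so free RNA and expression by Müller glia cannot be told apart.

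Other splits of the same libraries were counted, the real one included, to ask whether chance can give as many calls. They part libraries of a title, which the real split keeps together, so chance is called excluded only where splits of summed titles, added last, agree. Early against late it can be excluded in microglia (1 of 100 splits, real 2109 calls, highest other 671, and summed 1 of 100, 1067, 284), in astrocytes (1 of 100, 1603, 503, and 1 of 100, 799, 244) and in Müller glia (1 of 45, 95, 11, and 1 of 45, 54, 0). In Müller glia it cannot at 1 d (1 of 45, 2443, 1430, and 2 of 45, 2185, 2621), 4 d (1 of 45, 2449, 1814, and 2 of 45, 2444, 2552), 1 week (2 of 45, 569, 1333, and 1 of 45, 210, 68) and 2 weeks (1 of 45, 40, 13, and 4 of 45, 9, 46), as another split called more. It cannot at 2 d (9 of 45, 15, 2018), where edgeR called 0 genes with summed titles (1053 at an unadjusted p under 0.05), and up to 290 in 45 splits. In microglia it cannot at 2 d (3 of 35, 478, 809, and 1 of 10, 190, 0). Splits of summed titles are too few in microglia at 1 d (1 of 35, 1078, 412, and 1 of 10, 417, 2) and 2 weeks (2 of 100, 580, 733, and 1 of 10, 100, 19). They were not run with 2 titles in a group: in microglia at 1 week (1 of 35, 1066, 1, and 145 calls summed), and in astrocytes at 1 week (1 of 35, 785, 115, and 126 calls) and 2 weeks (1 of 35, 174, 18, and 30 calls). In astrocytes the 10 splits at 1 d (1 of 10, 314, 2) and 2 d (3 of 10, 61, 850) are too few. The first draw of libraries differed: it gave 1 of 35 at 2 weeks in microglia (highest other 99), and 2 of 30 at 2 weeks (870), 5 of 30 at 2 d and 1 of 30 at 1 week (21) in Müller glia. Its highest others early against late were 832 in microglia, 1 in astrocytes and 2 in Müller glia, and 199 and 67 in Müller glia at 1 d and 4 d. Splits that call several times the real count, as at 2 d in astrocytes and Müller glia, point to a structure of the libraries other than time, whose source was not tested.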

How the results depend on the processing

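The alternatives that add or drop cell classes, keep or drop the libraries sorted for RGCs and immune cells, or add a term for the RGC gate were chosen after seeing the data. Counts of called genes moved with the setting, and the cause was not tested except where fewer libraries or genes entered. Over the 6 times and then early against late, with the reported count in parentheses, C57BL/6J libraries alone gave in microglia 783 (1652), 142 (1078), 137 (478), 306 (1727), 69 (1066), 278 (580) and 463 (2109). In astrocytes they gave 1455 (2232), 107 (314), 17 (61), 736 (1858), 124 (785), 40 (174) and 311 (1603). Summed channels of a title gave in microglia 846, 417, 190, 844, 145, 100 and 1067. In astrocytes they gave 52 at 1 d, 1 at 2 d, 957 at 4 d, 126 at 1 week, 30 at 2 weeks and 799 early against late. In Müller glia they gave 0 at 2 d (15), 210 at 1 week (569), 9 at 2 weeks (40) and 54 early against late (95). A minimum of 200 cells gave in microglia 600, 289, 1122, 526 and 351 from 1 d to 2 weeks. It gave in astrocytes 123 at 1 d, 8 at 2 d and 357 at 1 week. In Müller glia it gave 267 at 12 h (769), 0 at 2 d, 29 at 1 week, 5 at 2 weeks and 17 early against late. A minimum of 20 cells gave 0 at 2 d in Müller glia. No filter on genes gave in microglia 827 at 2 d, 1649 at 1 week and 1420 at 2 weeks. In astrocytes it gave 749, 539, 1455 and 597 at 1 d, 2 d, 1 week and 2 weeks. In Müller glia it gave 1164, 413, 1640, 400 and 328 at 12 h, 2 d, 1 week, 2 weeks and early against late. DESeq2 gave in microglia 791 at 2 d and 912 at 2 weeks. In astrocytes it gave 661, 268 and 332 at 1 d, 2 d and 2 weeks, and in Müller glia 1173, 162, 1068, 92 and 178 at 12 h, 2 d, 1 week, 2 weeks and early against late. In RPE DESeq2 gave 5837 (9891), 2148 (4784) and 1179 (3919) at 12 h, 1 d and 2 d, and 6064 (9671) at 2 d against 12 h. Genes at 0.1 or more of their highest type gave 702 and 331 in microglia at 1 and 2 weeks, and 114, 457 and 975 in astrocytes at 2 d, 1 week and early against late. Without a strain term astrocytes gave 101 at 2 d and 330 at 2 weeks, and Müller glia 7, 126 and 155 at 2 d, 2 weeks and early against late. GLAST libraries alone gave 0 for the 7 Müller glia contrasts in edgeR, a void test as the spread is that of their 2 controls alone; their counts at an unadjusted p under 0.05 were 1469, 2788, 565, 3444, 1808, 344 and 412. The libraries sorted for RGCs and immune cells alone gave 4139 and 2706 in microglia at 1 d and 2 d, a void test as the spread is that of 2 libraries of a title. Without their 2 controls microglia gave 500, 1145 and 664 at 1 d, 4 d and 1 week, astrocytes 106, 21, 1191, 434 and 101 from 1 d to 2 weeks, and Müller glia 0 at 2 d and 16 at 2 weeks. Plain classes gave 166 in microglia and 0 in Müller glia at 2 d, and the RGC gate term 129 in astrocytes at 2 d. The 0 counts at 2 d in Müller glia are edgeR's, beside 162 by DESeq2 on all libraries and 1121 at an unadjusted p under 0.05.

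With the replicate number as a block, microglia gave 196 calls at 2 d and 1059 early against late. Astrocytes gave 1416, 153, 11, 929, 477 and 328 at 12 h, 1 d, 2 d, 4 d, 1 week and early against late, and Müller glia 0 at 2 d. Same-numbered libraries did not deviate together (correlations of -0.02 to 0.04 in microglia, 0 to 0.03 in astrocytes, -0.01 to 0.01 in Müller glia and -0.02 in RPE), so the numbers do not pair the libraries. Gene lists with an estimated correlation gave 8 pairs of list and time (88) in microglia, 17 (93) in astrocytes, 5 (81) in Müller glia, 0 (73) in RPE and 0 (13) in monocyte-derived cells.

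Leaving out each library in turn gave 847 to 1836, 358 to 1216, 297 to 798, 387 to 1921, 544 to 1274, 213 to 1136 and 898 to 2329 calls in microglia from 12 h to early against late. In astrocytes it gave 1399 to 2374, 69 to 1156, 21 to 212, 285 to 2618, 419 to 1241, 99 to 207 and 633 to 1818. In Müller glia it gave 141 to 894, 946 to 2780, 0 to 28, 772 to 2939, 142 to 851, 15 to 56 and 19 to 129. In RPE it gave 9068 to 9912 at 12 h, 5126 to 5481 at 1 d, 3547 to 4570 at 2 d and 8694 to 9028 at 2 d against 12 h, and in monocyte-derived cells 323 to 1605. Of the named genes that had been called, 59 of 92 in microglia, 75 of 91 in astrocytes, 90 of 90 in RPE (6 settings) and 10 of 10 in monocyte-derived cells (3 settings, against 14 to 16 in microglia) stayed called under every setting run, and 0 of 93 in Müller glia, which follows from the void fit of GLAST libraries. Of 2208, 2016 and 2035 values of named genes with a library left out in microglia, astrocytes and Müller glia, 56, 57 and 84 lost and 9, 5 and 1 gained a call. In the other settings 70 of 1422, 49 of 1199 and 126 of 1128 (that void fit included) lost and 10, 9 and 4 gained one.

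Some values reversed. Within the libraries sorted for RGCs and immune cells, microglial mt-Nd5 at 2 d was -0.54 (0.83), Rlbp1 at 2 weeks 1.24 (-2.74) and Spc25 at 2 weeks 1.46 (-2.83). In Müller glia at 12 h mt-Co1 was -0.74 with 200 cells and -0.29 in GLAST libraries (1.60), and -0.70 to 2.52 with a library left out, and in microglia -0.92 to 1.98. As a median score the interferon difference between microglia and astrocytes was 0.19 at 1 d (-0.13) and 0.0623 at 2 weeks (-0.20). With cells of the MC21 pair thinned to 1000 UMIs the log2 ratio of Gpnmb in T cells was -3.13 (-6.05), of Fabp5 in microglia -1.85 (-2.06) and of Acp5 in Ms4a7 macrophages -1.87 (-3.8). Reported values of shares, of differences between these types and of the MC21 pair were narrowed to those in the text after reversed ones had been listed. For shares 945 of 1161 values were left out, 24 of 24 reversed ones among them, for differences 105 of 121 and 15 of 17, and for the MC21 pair 79 of 139 and 16 of 16. Not run or without effect were the control libraries of other cells (no cells of these types), and in RPE summed channels (no residual degrees of freedom), free RNA and cell minimums.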
